A study of Mus musculus with 27 samples.

How the data were processed

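The samples were 27 Affymetrix arrays of mouse cerebellum, each hybridised with RNA from a single labelled sample. Tumours came from Math1-cre:SmoM2 (3), Tlx3-cre:SmoM2 (3), Olig2-tva-cre:SmoM2 (7), hGFAP-cre:SmoM2 (6) and Ptc1+/- (2) mice, and 6 samples were cerebellar tissue without tumour from 4 of the mouse lines. Per the labels' protocols, RNA was extracted with Trizol and RNeasy columns and 5 ug of total RNA was made into biotinylated cRNA by the standard Affymetrix procedure. The deposited values are linear signal intensities of 45101 probe sets computed with MAS5, per the submitters' processing notes, with the version and the scaling target not given in the sources used here. No detection calls were used here, so low values can be background.

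The arrays had not been brought to a common level, as their 2% trimmed means ran from 42.58 to 205.96 (a ratio of 4.84). Since these differed by more than the limit of 5% set beforehand, each array was rescaled to the common trimmed mean of 123.61. Signals below the 20th percentile of the table (10.3, or 3.37 on the log2 scale) were raised to that floor, and log2 values were taken. Probe sets were kept when above the median of the table (45.6) on at least 3 arrays, which left 30107. The probe annotation listed 35890 probe sets, of which 34958 had 1 gene and 932 several, and 9211 were not listed and stayed unnamed here. For each gene the probe set with the highest mean was used, which gave 13527 genes, so another transcript of the same gene can differ. Gene symbols were matched by Entrez number, for 34754 probe sets, with 0 renamed. The 64 control probe sets of the array maker were left out of the tests. No 2 arrays held identical values, and no value column was left unused.

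Groups were compared with limma in a single linear model with a mean for each of the 6 groups (21 residual degrees of freedom, moderated to a median of 28.2), with empirical Bayes moderation using a trend and a robust fit. All limma p-values were two-sided, except that of the F statistic over the 4 SmoM2 groups, and were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called at an adjusted p under 0.05. The contrasts were all tumour groups against tissue without tumour, each tumour group against it, hGFAP and Olig2 against Math1 and Tlx3, Ptc1+/- against the 4 SmoM2 groups, hGFAP against Olig2, and Tlx3 against Math1. All group means had equal weight within a contrast. Fold changes were not filtered.

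A set of 34 gene lists was tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with fry beside it, adjusted over the lists of a comparison. Members of each list were also counted over all genes and adjusted over the list alone. The share of expression differences between the SmoM2 groups was taken from Euclidean distances over all tested genes, with 100000 permutations of the labels, one-sided for a large share. List means per array were compared among the 4 groups by the F statistic with 100000 permutations. Pairs of groups used all splits of their arrays. Sharing of effects between tumour groups was set beside 20 simulations with unchanged groups and 20 splits of the controls, since the comparisons share control arrays.

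These tests, the gene lists and the genes to be named were chosen before the data were examined. The named genes were the 8 genes of the design, the 12 highest and 12 lowest in all tumours whose group means all lay on the same side, the 20 smallest p-values among the SmoM2 groups with means at least 2-fold apart, the 10 highest and 10 lowest in the next 2 contrasts, 5 and 5 between pairs of groups, 2 and 2 for each tumour group, and the extremes of each list. Xist, genes of the Y chromosome, haemoglobin genes and immunoglobulin genes were left out of all but the lists. Alternatives fixed beforehand changed the scaling, the floor, the filter, the choice of probe set, the arrays in the model, the moderation, the array weights, a block for the replicate number, the controls, the distance and the gene set, and left out each array in turn. Alternatives chosen after seeing the data used the 3' to 5' ratio or array brightness as a covariate, and left out the 5 arrays with a mean log2 ratio of Gapdh and Actb control probe sets over 1.25 or the 7 arrays with a trimmed mean under 85.

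The model was tested on simulated data with 200 changed genes in 5 simulations. There each gene had the same spread in every group and genes varied independently. The real groups differed in spread, with median correlations between arrays from 0.885 in Olig2 to 0.961 in Tlx3 tumours. The rates below therefore describe the simulated data and need not hold for these arrays. Genes changed 2-fold were recovered in 64.2% of cases for all tumours, 63.3% for hGFAP and Olig2 against Math1 and Tlx3, 53.7% for hGFAP against Olig2, 25.1% for Ptc1+/- against SmoM2 and 17.6% for Tlx3 against Math1, and false calls made up 4.9% of calls for all tumours and 8.1% for Ptc1+/- against SmoM2. The median standard error of a log2 difference over all tumours was 0.212. The sexes, read from Xist and genes of the Y chromosome, were mixed in every group. Work was done in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.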

Results

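Gene expression was measured on 27 Affymetrix arrays hybridised with total RNA from the mouse cerebellum. Of these, 19 held tumours of mice in which a cre driver switched on SmoM2, an activated form of the Hedgehog receptor component Smoothened. The drivers were Math1-cre (3 arrays), Tlx3-cre (3 arrays), Olig2-tva-cre (7 arrays) and hGFAP-cre (6 arrays). Another 2 arrays held tumours of Ptc1+/- mice, which carry a single working copy of Ptch1, the gene of the Hedgehog receptor Patched. The remaining 6 arrays held cerebellar tissue without tumour, 2 from Olig2-tva-cre:SmoM2, 1 from hGFAP-cre:SmoM2, 2 from Mxi1-cre:SmoM2 and 1 from Ptc1+/- mice. Math1 (Atoh1) marks the granule neuron lineage, and Olig2 and the human GFAP promoter are active in broader progenitor pools. The series title names the question as how granule neuron precursor identity relates to Hedgehog-induced medulloblastoma. Values were MAS5 signals, and the arrays differed in brightness, with trimmed mean signals from 42.58 to 205.96, so each array was rescaled before log2 values were taken. The number of arrays per group limits the precision. The labels call the tumours biological replicates without naming animals, so p-values measure the spread between these samples.

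The genes named by the design were read first. Gli1, a transcription factor and target of Hedgehog signalling, had a log2 signal of 5.93 ± 0.28 (SD, n = 6) in tissue without tumour and 9.37 ± 0.08 (SD, n = 3) in Math1 tumours. It was 3.13 higher over the tumour groups on the log2 scale (SE 0.30, limma adjusted p = 4.61e-10), and all 21 tumour arrays lay above every control array. Smo rose by 1.73 (adjusted p = 8.67e-11). Atoh1, the transcription factor that specifies granule neuron precursors, rose by 4.69 (SE 0.33, adjusted p = 9.97e-13). The gain of Atoh1 was 4.74 in Math1, 4.47 in Tlx3, 4.77 in Olig2, 4.17 in hGFAP and 5.28 in Ptc1+/- tumours. Olig2 rose by 2.54 (adjusted p = 1.95e-08), Gfap by 2.24 (adjusted p = 0.000253) and Tlx3 by 1.04 (adjusted p = 0.012). Without control array 6, where Tlx3 stood at 3.63, its difference was 0.58 (adjusted p = 0.0893), and its call was also lost without the 7 dimmest arrays. Mxi1, the driver gene of a line with no tumour array, differed by 0.27 (adjusted p = 0.176). Neither Olig2 nor Tlx3 was highest in the tumours of its own driver, since both had their highest group mean in Math1 tumours, at 8.20 ± 0.11 (SD, n = 3) for Olig2 and 7.55 ± 0.10 (SD, n = 3) for Tlx3. Where these probe sets lie relative to the cre constructs was not examined, so their signals do not check which driver a tumour carried.

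Ptch1 was lower in Ptc1+/- than in SmoM2 tumours with each of its 3 probe sets. On the probe set used here its log2 signal was 10.30 ± 0.24 (SD, n = 6) in tissue without tumour, between 11.27 and 11.67 as a mean in the 4 SmoM2 groups, and 8.89 ± 0.70 (SD, n = 2) in Ptc1+/- tumours. Against tissue without tumour, Ptch1 rose by 1.16 in Math1 (adjusted p = 0.00129), 0.97 in Tlx3 (adjusted p = 0.00641), 1.36 in Olig2 (adjusted p = 5.48e-06) and 1.14 in hGFAP tumours (adjusted p = 0.000151), and it fell by 1.41 in Ptc1+/- tumours (adjusted p = 0.000847). The fall against tissue without tumour was not shown by another probe set of Ptch1, which stood at 7.50 ± 0.93 (SD, n = 2) in Ptc1+/- tumours and at 6.56 ± 0.37 (SD, n = 6) in tissue without tumour. The single control array from a Ptc1+/- mouse stood at 10.42 on the main probe set, within the other control arrays (9.93 to 10.58). The low signal was thus seen in the Ptc1+/- tumours and not in the 1 control array of that genotype. The difference of the main probe set of Ptch1 over all 5 tumour groups was 0.64 (adjusted p = 0.00458).

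**Figure D1:**
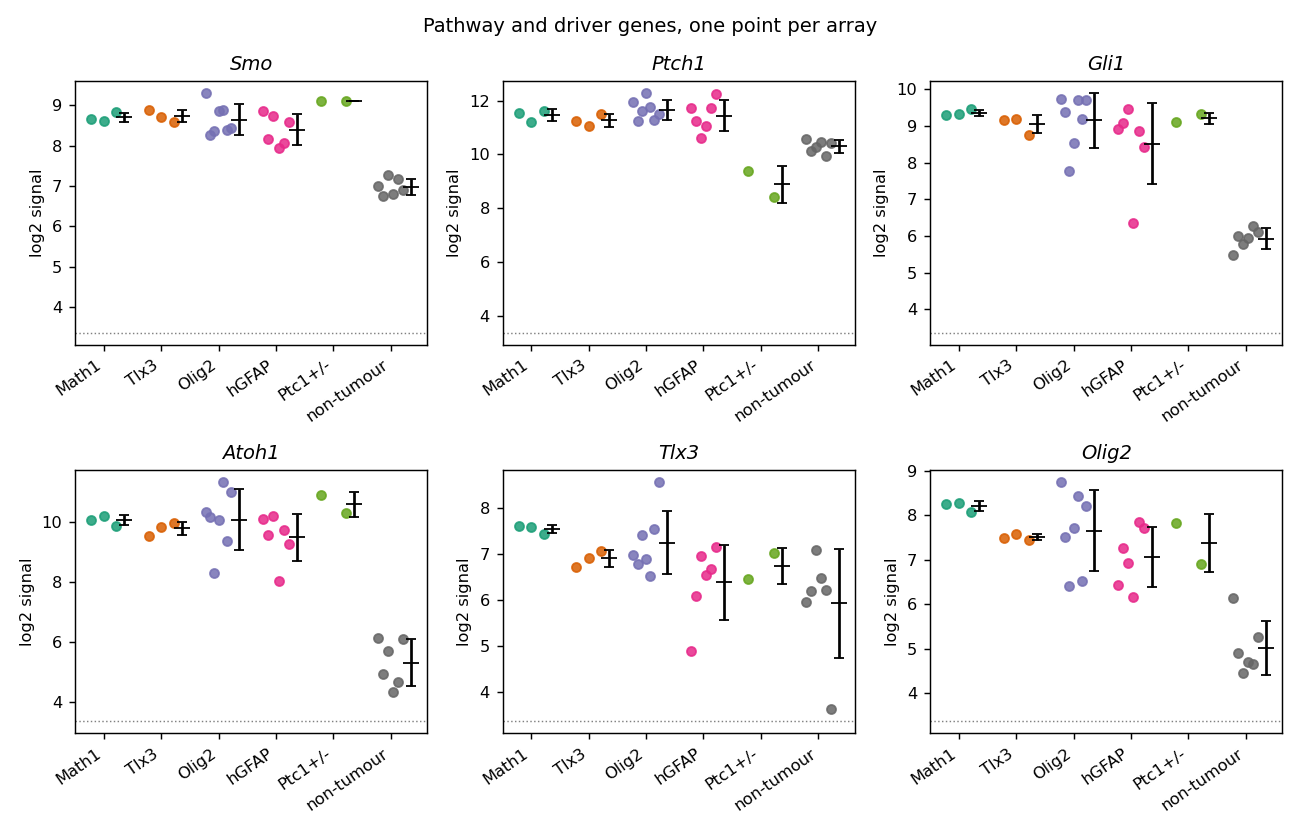
Log2 signal of Smo, Ptch1, Gli1, Atoh1, Tlx3 and Olig2 on each of the 27 arrays by group, with group mean and SD as black bars beside the points and the signal floor of 3.37 as a dotted line. All 21 tumour arrays lie above all control arrays for Gli1 and Atoh1, and the 2 Ptc1+/- tumour arrays lie below every other array for the main probe set of Ptch1.

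All tumours were compared with tissue without tumour to find what the tumours share, each tumour group having equal weight. Neural precursor and cell cycle genes headed the increases. Insm1, a zinc finger factor of neuronal progenitors, rose by at least 7.17 on the log2 scale (SE 0.36, adjusted p = 6.14e-16), a lower bound since 4 of the 6 control arrays were at the floor. Sox11 rose by 6.53, Mki67 by 6.29, Cdk6 by 6.21, Cd24a by 6.20, Top2a by 6.15, Tox3 by 5.88, Dcc by 5.79, Cks2 by 5.71, Ccnd2 by 5.65 and Ube2c by at least 5.63, with 3 of the 6 control arrays at the floor. Cdca3 rose by at least 5.83, with 4 control arrays at the floor, a direction shown by 1 of its 3 probe sets. Mki67 and Tox3 had 1 control array each at the floor, so their gains are lower bounds too. Markers of differentiated cerebellar neurons headed the decreases. Gabra6, a GABA receptor subunit of mature granule neurons, fell by 5.46 (SE 0.56, adjusted p = 2.13e-09). Also lower were Vsnl1 (-5.34), Tesc (-5.29), Cbln3 (-5.17), Chn2 (-4.96), Pcp2 (-4.92), Eno2 (-4.90), Car8 (-4.90), Gng13 (-4.88), Rgs8 (-4.85) and Rnf112 (-4.84). Slc1a6, a glutamate transporter of Purkinje cells, fell by at least 5.27, since all arrays of the Math1 and Ptc1+/- tumours were at the floor. Tesc, Pcp2, Eno2 and Rnf112 had a tumour array at the floor in at least 1 group and fell by at least as much. Of 13527 genes tested, limma called 7092 at an adjusted p under 0.05, 3630 higher and 3462 lower, and 3680 of them differed at least 2-fold.

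Hedgehog targets rose together. Of the 12 measured genes of Hedgehog output, 10 rose and 1 fell (camera adjusted p = 1.24e-06). Ccnd2 rose by 5.65, Sfrp1 by 5.56, Pdlim3 by at least 5.30, with 3 of the 6 control arrays at the floor, and Mycn by 4.65, Bcl2 stood at 0.04 (adjusted p = 0.83), and Eya1 fell by 0.58. Of 14 Hedgehog pathway components 8 rose and 3 fell, a list that did not pass (adjusted p = 0.176). There Kif7 rose by at least 2.31, with 5 control arrays at the floor, and Sufu by 2.14, while Cdon, a co-receptor, stood lower at -2.65 and Shh at -1.82. Of 14 granule neuron precursor genes 11 rose and 1 fell (adjusted p = 5.17e-06), with Insm1 and the chemokine receptor Cxcr4, at 4.76, highest, Neurod1 at -0.48 (adjusted p = 0.0707) and Zic2 lower by -0.64. Of 10 genes of migrating granule neurons 5 rose and 2 fell (adjusted p = 0.118). Dcc, a netrin receptor, rose by 5.79 and the microtubule protein gene Dcx by 5.53, while Stmn2 was lower at -1.20 and Unc5c at -1.39. Of 6 genes of other rhombic lip derivatives 5 rose and 1 fell (adjusted p = 0.0155, and adjusted p = 0.0959 with an estimated correlation). These were Pou4f1 at 4.08, Lhx2 at 3.70, Olig3 at 3.06, Otx2 at 2.68, Tlx3 at 1.04 and Eomes at -1.69. The gains of Lhx2 (6 control arrays at the floor), Olig3 (2), Pou4f1 and Dcx (1 each) are lower bounds, and Cdon and Eomes, with 1 tumour array at the floor, fell by at least as much.

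Cell division genes rose almost without exception. Of 26 mitosis genes 25 rose and Tpx2 did not pass, at 0.06 (camera adjusted p = 5.72e-23). The smallest called gain was that of Foxm1, at 1.31. Of 24 DNA replication genes 22 rose (adjusted p = 4.64e-16), with Rrm2 at 5.61 and Uhrf1 at 5.50 or more, with 3 control arrays at the floor. Ccne1, at 0.14, and Fen1, at -0.24, did not pass, and the mean of the probe sets of Fen1 gave the opposite sign, 0.85. Of 14 ribosome biogenesis genes 13 rose, led by Nop58 at 2.21 and Nhp2 at 2.17, with Nop2 at 0.55 and Polr1b, which did not pass, at 0.29. The list had an adjusted p = 6.02e-05, and an adjusted p = 0.0959 with an estimated correlation. Of 12 polycomb and DNA methylation genes 9 rose and 1 fell (adjusted p = 0.0015, and adjusted p = 0.117 with an estimated correlation). Ezh2, the histone methyltransferase of the complex, rose by 3.49 and Bmi1 by 1.58, Ring1 stood at -0.45 (adjusted p = 0.36), and Dnmt3a fell by 0.78. Of 12 p53 targets 4 rose and 3 fell (adjusted p = 0.492), from Eda2r at 3.39 and Trp53inp1 at 1.74 to Perp at -1.36 and Plk2 at -1.62, the last 2 and Eda2r being bounds, with arrays of the lower side at the floor.

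Progenitor and signalling lists were read next. Of 12 neural stem cell genes 7 rose and 1 fell (camera adjusted p = 0.0865), with Melk at 4.10 or more, as all 6 control arrays were at the floor, and Hes5 at 2.05, with 3 control arrays and 1 Olig2 array at the floor. Nes stood at -0.41 (adjusted p = 0.18), where the mean of its probe sets gave 1.02, and Prom1 fell by 0.51. Of 11 Notch signalling genes 6 rose and none fell (adjusted p = 0.00845, and adjusted p = 0.263 with an estimated correlation). The Notch ligand genes Dll3 and Jag1 rose by 2.50 and 2.32, while Lfng, at 0.20, and Dll1, at -0.02, did not pass. Of 7 Wnt output genes 2 rose, Nkd1 by 2.64 and Lgr5 by 0.59 (adjusted p = 0.378 for the list). Notum, at -0.34, and Lef1, at -0.46, did not pass. Of 8 oligodendrocyte precursor genes 6 rose (adjusted p = 0.00549, and adjusted p = 0.0829 with an estimated correlation). These were Pdgfra at 4.33, Olig2 at 2.54, Olig1 at 1.51, Gpr17 at 1.38, Vcan at 1.18 and Cspg4 at 0.85, while Sox10, at 0.18, and Nkx2-2, at -0.38, did not pass.

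Genes of differentiated neurons and glia fell. All 12 measured genes of mature granule neurons fell (camera adjusted p = 1.06e-08, and adjusted p = 0.0829 with an estimated correlation), from Rbfox3 at -0.98 and Neurod2 at -2.21 to Cbln3 at -5.17 and Gabra6 at -5.46. All 10 Purkinje cell genes fell (adjusted p = 1.09e-08, and adjusted p = 0.0755 with an estimated correlation), from Dner at -2.27 and Homer3 at -2.36 to Pcp2 at -4.92 and Slc1a6 at no more than -5.27. All 9 GABAergic interneuron genes fell (adjusted p = 3.96e-07, and adjusted p = 0.0557 with an estimated correlation). Among these, Gad1, the gene of an enzyme of GABA synthesis, stood at -4.68, Pvalb at -4.12, Grm2, with arrays of both sides at the floor, at -1.88 and Npy at -1.47. Of 15 genes of synaptic vesicles and release 14 fell (adjusted p = 7.16e-08, and adjusted p = 0.0557 with an estimated correlation), among them Syt1 at -3.63, Nsf and, least, Cplx2 at -1.10, while Stx1a rose by 1.90. Of 13 oligodendrocyte genes 12 fell (adjusted p = 3.25e-07, and adjusted p = 0.0755 with an estimated correlation), including Ermn at -3.24 or lower, with tumour arrays of every group at the floor, the myelin gene Mbp at -3.22 and Opalin at -1.39, and Gjc3, at -0.46, did not pass. Of 16 genes of astrocytes and Bergmann glia 13 fell and 2 rose (adjusted p = 0.001, and adjusted p = 0.0829 with an estimated correlation). Gdf10 stood at -2.76 and Gjb6 at -2.65, whereas Gfap rose by 2.24 and Slc6a11 by 1.42.

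Genes of myeloid cells were higher in the tumours. Of 13 microglia and macrophage genes 12 rose (camera adjusted p = 2.17e-06, and adjusted p = 0.0829 with an estimated correlation), led by Lyz2 at 3.99 and the complement gene C1qc at 3.46. Csf1r rose by 0.50 and P2ry12, at 0.43, did not pass. Of 4 lymphocyte genes Ptprc rose by 1.37 and Cd52 by 1.08, and Cd8a, at 0.26, and Ighm, at 0.06, did not pass (adjusted p = 0.234 for the list). Of 10 antigen presentation genes 5 rose and 1 fell (adjusted p = 0.273). H2-Ab1 rose by 1.42, Psmb8 by 1.19, H2-Aa by 1.14, H2-Eb1 by 0.79 and H2-K1 by 0.73, Tap1 stood at 0.14 (adjusted p = 0.693), and H2-D1 fell by 0.59. Of 12 interferon response genes Ifit3 fell by 0.87 and none rose (adjusted p = 0.855), with Bst2 at 0.78, where arrays of both sides were at the floor as for H2-Ab1 and Psmb8, Rsad2 at 0.30 and Gbp2 at -0.31.

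Vessel and other lists gave small or mixed differences. Of 9 endothelial genes 3 fell, Tek at -1.09, Flt1 at -0.93 and Slco1c1 at -0.48 (camera adjusted p = 0.329), with Kdr at 0.25 and Cdh5 at 0.04. Of 11 mural and mesenchymal genes 4 rose and 2 fell (adjusted p = 0.901). Col4a1, a basement membrane collagen gene, rose by 2.18, Col3a1 by 1.11, Lum by 0.91 and Dcn by 0.55, while Rgs5 fell, at -0.55, and Pdgfrb, at -1.54. The median of this list was -0.07 and its mean 0.15. No gene of the 6 of choroid plexus (adjusted p = 0.857), the 2 of blood (adjusted p = 0.71) or the 4 sex-linked genes (adjusted p = 0.851) passed. In these, Ttr stood at 1.93 (adjusted p = 0.396), Folr1 at 0.43, Aqp1 at 0.07, Kcnj13 at -0.68, S100a9 at 0.76, S100a8 at 0.74, Xist at 0.53, Eif2s3y at -0.36, Uty at -0.45 and Kdm5d at -0.72. Of 7 ependymal genes 2 fell, Dynlrb2 at -0.76 and Ccdc153 at -0.83 or lower, with 5 of the 7 Olig2 arrays at the floor (adjusted p = 0.451), with Foxj1 at 0.61, Cfap126 at -0.11, Tmem212 at -0.86 and Dnah6 at -0.95.

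Metabolic and activity lists were mixed as well. Of 12 hypoxia and glycolysis genes 2 rose and 7 fell (camera adjusted p = 0.0865). Hk2, the gene of a hexokinase, rose by 2.41 and Ldha by 0.80, while Bnip3 was lower at -1.96 and Ndrg1 at -2.04. Of 17 oxidative phosphorylation genes 7 fell (adjusted p = 0.0307, and adjusted p = 0.388 with an estimated correlation), with Atp5j at 0.04, Ndufs4 at -0.05, Ndufb8 lower by -0.88 and Ndufa5 lower by -0.94. Of 12 cholesterol synthesis genes 4 rose and 2 fell (adjusted p = 0.62). Cyp51 rose by 1.13, Sqle by 1.06, Fdps by 0.72 and Fdft1 by 0.64, while Hmgcs1 was lower at -0.44 and Sc5d at -1.26. Of 7 immediate early genes 2 rose and 4 fell (adjusted p = 0.438). Egr2 rose by at least 1.87, with 3 control arrays at the floor, and Ier2 by 0.54, while Egr1 was lower at -2.35, Fos at -1.47, Nr4a1 at -1.46 and Dusp1 at -0.89. Adjusted over the list alone, the counts of called genes in this comparison were those given above, with exceptions in 5 of the 34 lists. Adjusted over the list alone, 2 granule neuron precursor genes fell, 3 mural genes fell, 5 cholesterol genes rose, 5 oxidative phosphorylation genes fell and 0 ependymal genes passed, limma giving 2 ependymal genes over all genes tested.

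**Figure D2:**
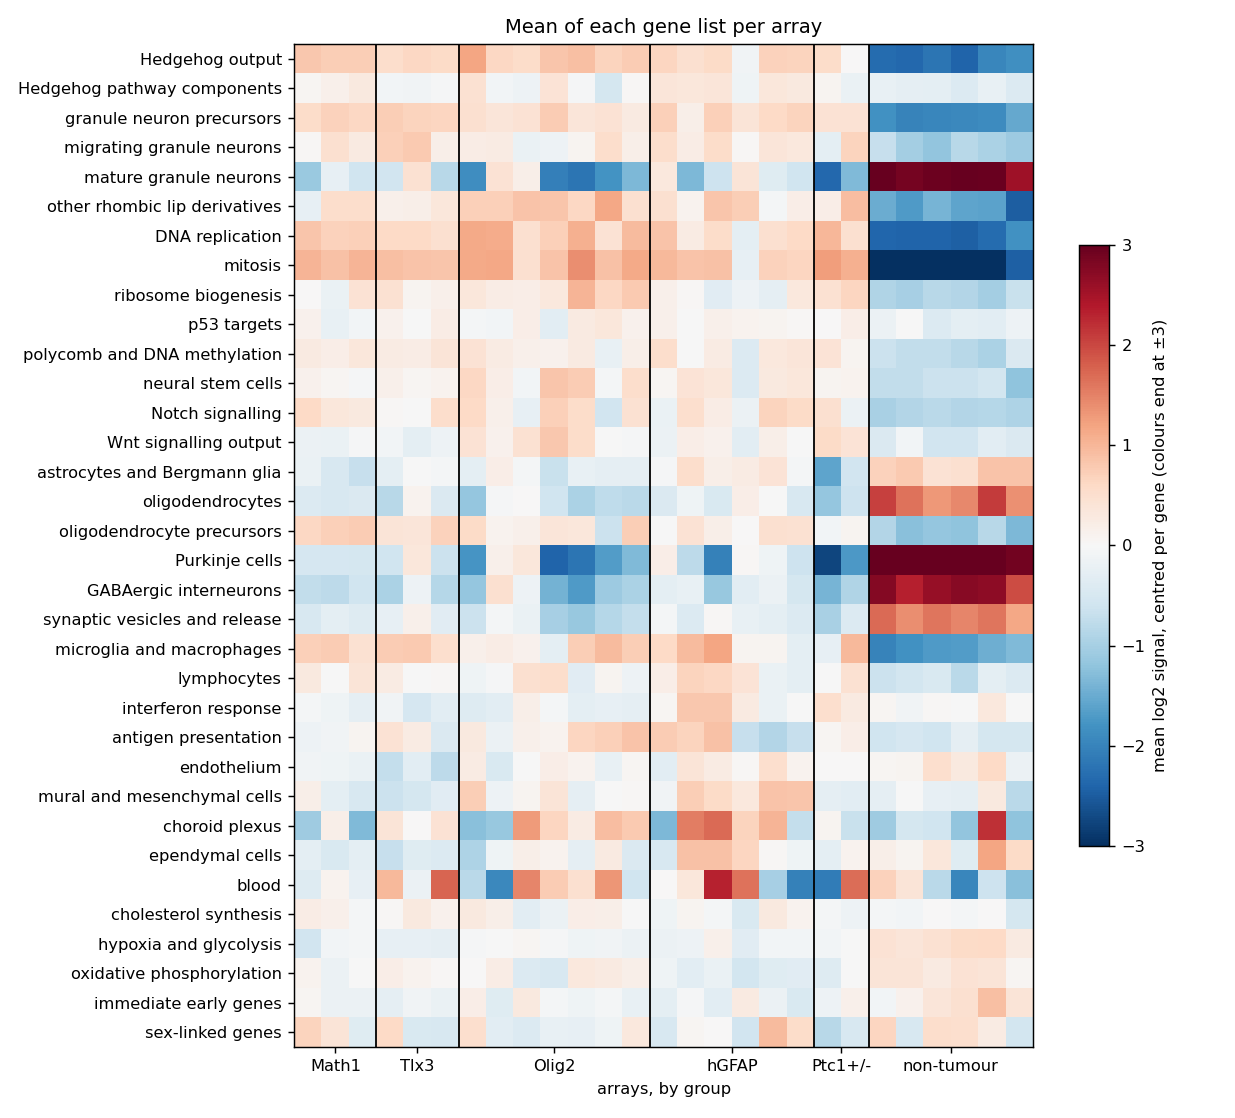
Mean log2 signal of each of the 34 gene lists on each array, centred per gene over the 27 arrays, with arrays in columns by group and colours ending at 3 units either way. Mitosis and DNA replication are low and mature granule neurons and Purkinje cells are high on the 6 control arrays.

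Each tumour group was also set against tissue without tumour, to see whether the groups moved the same genes. Insm1, with 4 of the 6 control arrays at the floor, had the largest increase in every group, by at least 7.16 in Math1, 6.86 in Tlx3, 7.39 in Olig2, 7.45 in hGFAP and 6.97 in Ptc1+/- tumours. Sox11 came next in Math1, at 6.44, in Tlx3, at 6.78, and in hGFAP tumours, at 6.97, and Mki67 came next in Olig2, at 6.55, and in Ptc1+/- tumours. Slc1a6 was lower in Math1, at no more than -5.62, in Tlx3, at no more than -5.04, and in hGFAP tumours, at no more than -5.33, with 3 of 3, 1 of 3 and 3 of 6 arrays at the floor, and Tesc stood at -5.28, -4.93 and -4.80 in the same groups. Gabra6 stood at -6.08 in Olig2 and -7.34 in Ptc1+/- tumours, where the next were Vsnl1, which fell by 5.66, and Car8, which fell by 7.29. Limma called 5062 genes in Math1, 5451 in Tlx3, 6714 in Olig2, 5645 in hGFAP and 4910 in Ptc1+/- tumours. Of 8620 genes called in at least 1 group, 3228 were called in the same direction in all 5, 1639 higher and 1589 lower, and 13 were called in opposite directions in some pair of groups.

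Log2 fold changes of the groups correlated across genes with r from 0.871 to 0.946, where genes are not independent replicates. The 5 comparisons share the 6 control arrays, and unchanged groups simulated against those arrays gave r from 0.284 to 0.516 and 0 shared calls by limma. Covariances were 1.18 to 1.56 against at most 0.046 in the simulation. With the controls split into 2 separate sets the correlations were 0.837 to 0.912, and independent lists of these sizes would share 5.1 higher and 4.5 lower genes. The simulated groups and the independent lists hold no shared tumour effect. They cannot show whether the groups share more than a general difference between tumour and cerebellar tissue. The tumours and the controls lay apart on the first principal component, which held 46.6% of the variance.

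**Figure D3:**
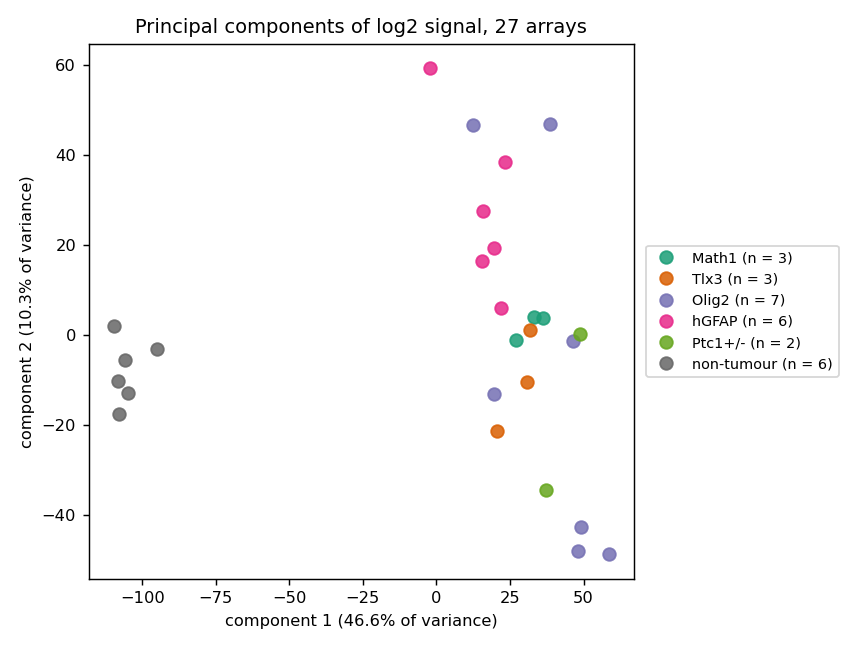
Position of the 27 arrays on the first and the second principal component of log2 signal over 13527 genes, which hold 46.6% and 10.3% of the variance, with a point per array coloured by group. The 6 control arrays lie between -110 and -95.1 on component 1 and all tumour arrays between -2.30 and 58.6, where the groups overlap.

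The 4 SmoM2 groups were compared to ask whether tumours started by different drivers differ in expression. Few genes separated them with all arrays and the processing chosen, and the count moved widely in other settings, as given below. Itih3, which encodes a heavy chain of a hyaluronan-binding inhibitor complex, had means of 5.80 ± 0.13 (SD, n = 3) in Math1, 6.48 ± 0.86 (SD, n = 3) in Tlx3, 7.93 ± 0.49 (SD, n = 7) in Olig2 and 8.80 ± 0.60 (SD, n = 6) in hGFAP tumours (limma adjusted p = 0.000979). Pltp, a phospholipid transfer protein gene, followed the same order of hGFAP and Olig2 above the others, at 9.36, 8.78, 8.05 in Math1 and 7.77 in Tlx3 (adjusted p = 0.00387). Ccnd1, the gene of cyclin D1, was highest in Olig2 tumours, at 11.39 against 10.24 to 10.64 elsewhere (adjusted p = 0.00387). Gli3, a Hedgehog pathway transcription factor, was highest in hGFAP tumours, at 7.57 ± 0.50 (SD, n = 6), and lowest in Math1 tumours, at 5.34 ± 0.74 (SD, n = 3, adjusted p = 0.00827). The highest means of Csf1r, Slc13a3, Plpp3, Tube1 and Atp13a5 were in hGFAP tumours, at 10.82, 6.53, 9.93, 8.26 and 5.78. Those of Epha3, Cltb, Gmps and Acot7 were in Olig2 tumours, at 8.26, 10.29, 9.34 and 8.84. Adck5, Lap3 and Ehbp1 were highest in Math1 tumours, at 8.86, 9.53 and 10.10, and Pag1, Nexmif, Car10 and Nol4l in Tlx3 tumours, at 8.66, 8.33, 7.90 and 7.86.

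Limma called 128 genes for a difference among these 4 groups, of which 116 had group means at least 2-fold apart. The count moved by over 1.5 times without Math1 array 3 (83), Tlx3 array 1 (63) or 2 (41), Olig2 array 2 (340), 3 (455), 4 (356), 5 (45), 6 (82) or 7 (44), or hGFAP array 5 (44) or 6 (85). The driver accounted for 24.4% of the summed squared distances between the 19 arrays, where permuted labels gave 16.7% on average (permutation p = 0.0157, one-sided). Without Tlx3 array 1 the permutation p was 0.0507, and without Tlx3 array 2 it was 0.0618. With a correlation distance the share was 24.4% with a permutation p = 0.105. Arrays of the same group had a median correlation of 0.903, and SmoM2 arrays of different groups 0.904. The first value pools unlike groups, with medians of 0.947 in Math1, 0.961 in Tlx3, 0.885 in Olig2 and 0.888 in hGFAP tumours. In the 6 pairs of groups, none passed after adjustment, the smallest exact permutation p being 0.0119 for Tlx3 against hGFAP (adjusted p = 0.0714). With 84 splits this is the lowest p that pair can give, so it could not pass on its own after adjustment. Math1 against Tlx3, with 20 splits, was also at its lowest possible exact permutation p, 0.1. The test therefore decides nothing for either pair. Olig2 against hGFAP, with 1716 splits, could have passed and gave an exact permutation p = 0.0332 (adjusted p = 0.0996). The ratio of 3' to 5' signal of control transcripts, a measure of RNA integrity, averaged 0.17 on the log2 scale in Math1, 0.28 in Tlx3, 0.51 in Olig2 and 1.05 in hGFAP tumours, and it accounted for 22.1% of the distances (permutation p = 1e-05, the smallest the permutations can give). Array brightness accounted for 12.8% (permutation p = 0.00336). With brightness removed the driver share was 21.0% (permutation p = 0.103), and with the ratio removed it was 23.6% (permutation p = 0.0111). Among alternatives chosen after seeing the data, it was 34.7% (permutation p = 0.0034) without the 4 SmoM2 arrays of high ratio and 34.0% (permutation p = 0.014) without the 6 dimmest SmoM2 arrays. Permuted labels also give a larger share on average with fewer arrays, so these 2 shares cannot be read against the 16.7% or 24.4% of 19 arrays.

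List means of the same 19 arrays gave no list past the adjusted threshold. Without the 4 SmoM2 arrays of high 3' to 5' ratio, left out after seeing the data, oxidative phosphorylation passed, with group means over a range of 0.46 (permutation p = 0.00103, adjusted p = 0.035), against a range of 0.43 with all arrays (adjusted p = 0.196). Mural and mesenchymal genes came nearest, with group means of 0.44 ± 0.38 (SD, n = 6) in hGFAP, 0.02 ± 0.34 (SD, n = 7) in Olig2, -0.30 ± 0.34 (SD, n = 3) in Math1 and -0.61 ± 0.14 (SD, n = 3) in Tlx3 tumours (permutation p = 0.00309, adjusted p = 0.063). Endothelial genes ranged over 0.77 between group means (permutation p = 0.00556) and astrocyte genes over 0.67 (permutation p = 0.00445), both with an adjusted p = 0.063 and both highest in hGFAP tumours, which also had the highest 3' to 5' ratio. After quantile normalization the endothelial range was 0.46 (permutation p = 0.0468, adjusted p = 0.199), while the mural range was 0.97 and the astrocyte range 0.71. Hedgehog output ranged over 0.30 (permutation p = 0.112) and granule neuron precursor genes over 0.23 (permutation p = 0.202).

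Tumours of the hGFAP and Olig2 drivers were then set against those of the Math1 and Tlx3 drivers, since the former are active in broader progenitors and the latter in the granule lineage as far as background knowledge goes. Itih3 was higher by 2.22 on the log2 scale (SE 0.28, adjusted p = 0.000151), and 12 of the 13 hGFAP and Olig2 arrays exceeded all 6 others. Pltp was higher by 1.16 (SE 0.17, adjusted p = 0.00103), in 13 of 13 arrays. In tissue without tumour the mean was 8.6 for Itih3 and 10.27 for Pltp, above the means of the Math1 and Tlx3 tumours. For Pltp it also lay above the means of hGFAP (9.36) and Olig2 tumours (8.78), so Pltp was not raised over that tissue in either. For Itih3 it lay between Olig2 (7.93) and hGFAP tumours (8.80), so the contrast alone does not show a rise over that tissue. Entpd2 was higher by 1.53, Cd72 by 1.21, Gli3 by 1.21, Gpank1 by 1.17, Tek by 1.14, Col6a1 by 1.09, Csgalnact1 by 0.99 and Gmps by 0.93, the directions of Gpank1 and Gmps being shown by 1 of 2 and 1 of 3 probe sets. Entpd2, Cd72 and Tek had 1 array at the floor in Math1 or Tlx3 tumours, so their values are lower bounds. The mean of tissue without tumour was above those of both hGFAP and Olig2 tumours for Entpd2, Tek and Gmps. It was below both for Cd72, Col6a1 and Csgalnact1, and between them for Gli3 and Gpank1. Otx1, a homeobox factor, was at -2.33 or lower, with 4 of the 7 Olig2 arrays at the floor, and Mir124-2hg at -1.92 or lower, with 1 hGFAP array there. Aff3 was lower by -1.21, Kcnk1 by -1.19, Ehbp1 by -1.14, Vxn by -1.08, Csrnp3 by -1.02, Abcd2 by -0.96, Ralgapa2 by -0.90 and Exoc8 by -0.83. Gli1, Atoh1 and Olig2 differed by -0.37 (adjusted p = 0.582), -0.14 (adjusted p = 0.882) and -0.50 (adjusted p = 0.433). Limma called 35 genes, 16 higher and 19 lower. Only Itih3 and Pltp, of the 20 genes named here, kept their call in all 35 alternatives, and 17 lost it in most of them. The count was 4 after quantile normalization, with 75% of calls higher in place of 45.7%, and 2 after centring on array medians, both higher. It moved by over 1.5 times without Math1 array 1 (2), 2 (3) or 3 (2), Tlx3 array 1 (2), 2 (2) or 3 (4), Olig2 array 2 (81), 3 (3), 4 (3), 5 (14) or 7 (4), or hGFAP array 2 (3), 4 (3), 5 (15) or 6 (3).

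Lists of vessel and other cell types were read in the same contrast. Mural and mesenchymal genes had a median of 0.64 (camera adjusted p = 7.21e-06), but with an adjusted p = 0.283 with an estimated correlation. Of the 11 genes none passed over all genes by limma, where 2091 of 13527 genes had an unadjusted p under 0.05, and 10 were higher adjusted over the list alone. Igf2 stood at 1.31 (adjusted p = 0.0929), Col3a1 at 1.23 (adjusted p = 0.0929), Lum at 0.50 and Rgs5 at -0.24. Endothelial genes had a median of 0.24 (adjusted p = 0.00972, and adjusted p = 0.524 with an estimated correlation), and Tek was the member called. Purkinje cell genes had a median of -0.61 (adjusted p = 0.0375, and adjusted p = 0.598 with an estimated correlation), with Pcp2 at -1.25 and Car8 at -0.84. Oligodendrocyte precursor genes had a median of -0.40 (adjusted p = 0.0483, and adjusted p = 0.524 with an estimated correlation), with Pdgfra at -0.87 (adjusted p = 0.079). By fry the mural (fry adjusted p = 0.0115) and endothelial lists (fry adjusted p = 0.0245) passed. The Purkinje cell (fry adjusted p = 0.383) and oligodendrocyte precursor lists (fry adjusted p = 0.146) did not. Of the other 30 lists none passed, among them Hedgehog output with a median of 0.04 (adjusted p = 0.989), mitosis with -0.13 (adjusted p = 0.299) and granule neuron precursors with -0.21 (adjusted p = 0.161). Gli3 and Slc1a3, at 0.67, were the other called list members.

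hGFAP tumours were compared directly with Olig2 tumours. Fat2, a cadherin of granule cells, was higher in hGFAP tumours by at least 2.78 on the log2 scale (SE 0.66, adjusted p = 0.0253), with 4 of the 7 Olig2 arrays at the floor, Prune2 by 2.60, Mndal by at least 2.57 (1 Olig2 array there), B3galt1 by at least 2.48 (2 there) and Rpgrip1 by 2.34. BC034090 was at -2.51 or lower, with 1 hGFAP array at the floor, and lower were the ephrin receptor genes Epha3 and Epha8 by -1.86 and -1.82, Pdlim3 by -1.79 and Art3 by -1.68 (SE 0.33, adjusted p = 0.00948), the last in 7 of 7 Olig2 arrays. None of these 10 genes kept its call in every alternative, and Mndal lost it in 22 of 29 and Rpgrip1 in 16 of 29. Limma called 404 genes, 259 higher and 145 lower, and after centring on array medians 39.5% of the calls were higher in place of 64.1%. Arrays were less alike within Olig2 (median r = 0.885) and hGFAP tumours (0.888) than within Math1 (0.947), Tlx3 (0.961) or control arrays (0.949). The model shares an estimate of each gene's spread over all groups. With only the compared groups in the model the count was 0 by limma. The count was also 0 without the 7 dimmest arrays, 5 of which were Olig2 arrays. It moved by over 1.5 times without Olig2 array 2 (696), 3 (1395), 4 (1246), 5 (93), 6 (140) or 7 (82), or hGFAP array 2 (267), 3 (180) or 5 (137).

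Tlx3 tumours against Math1 tumours gave 0 genes by limma, with 576 of 13527 at an unadjusted p under 0.05. Arrays had equal weight in this fit, and genes were called when arrays were weighted, as the section on processing gives. The median of all genes was -0.031 and became 0.085 after centring on array medians. Genes changed 4-fold in simulated data for this comparison were found in 71.2% of cases and those changed 2-fold in 17.6%. In such data differences of 2-fold were mostly not detectable with 3 arrays a group. The simulation gave every group the same spread, so these rates need not hold for the arrays here. The 3 against 3 arrays allow an exact permutation p of no less than 0.1 for any single value.

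Ptc1+/- tumours were compared with SmoM2 tumours, which activate the same pathway at another step. Ptch1 was lower by -2.57 on the log2 scale (SE 0.29, adjusted p = 1.21e-05), and all 19 SmoM2 arrays exceeded both Ptc1+/- arrays. Aqp4, the water channel of astrocytes, was lower by -2.74 (SE 0.32, adjusted p = 1.21e-05), again below all 19 arrays. Gas7 was lower by -3.71, Agt by -2.91, Thrsp by -2.57 (1 of 2 probe sets), Borcs7 by -2.53, the gap junction gene Gja1 by -2.39, Ndn by -2.36 and Kalrn by -2.34, and Grm3 was at -2.35, with both Ptc1+/- arrays and 1 Olig2 array at the floor. Thrsp, Borcs7 and Kalrn had 1 Ptc1+/- array at the floor, so they were lower by at least as much. Foxd1, a forkhead factor, was higher by at least 4.03 (3 of 7 Olig2 arrays and 1 hGFAP array at the floor, SE 0.57, adjusted p = 0.000444), at 8.46 ± 0.12 (SD, n = 2) against group means of 3.93 to 4.98. Prl, the gene of the pituitary hormone prolactin, was higher by at least 2.67, with arrays of all 4 SmoM2 groups at the floor (adjusted p = 0.0164), Numbl by 1.29, Gm26588 by 1.05, Sgce by 1.00 and Hdhd5 by 0.90. The other design genes did not pass, with Gli1 at 0.20 (adjusted p = 0.898), Smo at 0.48 (adjusted p = 0.432) and Atoh1 at 0.74 (adjusted p = 0.589). Limma called 74 genes, 6 higher and 68 lower (8.1% higher). The balance was 50 higher and 76 lower (39.7%) without the filter on dim probe sets, and 22 higher and 35 lower (38.6%) with the floor at the 40th percentile. Of the 16 genes named by rule Foxd1, Aqp4 and Ptch1 kept their call in every alternative, and the count moved by over 1.5 times without Ptc1+/- array 1 (137) or 2 (35), Math1 array 1 (43) or 2 (45), or Tlx3 array 2 (43). With a Ptc1+/- array left out, the lone array is assumed to vary like the other groups.

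Several glial and neuronal lists had lower medians in Ptc1+/- tumours. Astrocyte and Bergmann glia genes had a median of -1.02 (camera adjusted p = 2.33e-07, and 0.0309 with an estimated correlation), with 3 of 16 called, Aqp4, Gja1 and the bicarbonate transporter gene Slc4a4 at -1.63, and 8 adjusted over the list alone, while Slc6a11 stood at 1.11 and Slc1a2 at 0.39. Purkinje cell genes had a median of -1.60 (adjusted p = 1.36e-06, and adjusted p = 0.38 with an estimated correlation), with 7 of 10 lower adjusted over the list alone. Over all genes limma called 0 of these 10 and 0 of 12 mature granule neuron genes, where 1587 of 13527 genes had an unadjusted p under 0.05. Car8 stood at -2.99 (adjusted p = 0.152) and Pcp2 at -2.95 or lower, with 1 of the 2 arrays at the floor (adjusted p = 0.136). Mature granule neuron genes had a median of -1.05 (adjusted p = 3.92e-05, and adjusted p = 0.485 with an estimated correlation), with Gabra6 at -2.36 and Cbln3 at -2.31, and 6 of 12 lower adjusted over the list alone. Of 13 oligodendrocyte genes 3 were lower, Cldn11 by -1.61, Mag by -1.55 and Cnp by -1.55 (adjusted p = 0.0434, and adjusted p = 0.763 with an estimated correlation). Lower medians were also found for synaptic vesicle genes, at -0.16 (adjusted p = 0.0434), and oligodendrocyte precursor genes, at -0.39 (adjusted p = 0.0477). Higher medians were found for mitosis, at 0.32 (adjusted p = 0.0291), ribosome biogenesis, at 0.23 (adjusted p = 0.0219), interferon response, at 0.39 (adjusted p = 0.0434), and Wnt output, at 0.31 (adjusted p = 0.0434). With an estimated correlation these became an adjusted p = 0.763 for synaptic vesicles and for mitosis, adjusted p = 0.485 for oligodendrocyte precursors and interferon response, adjusted p = 0.579 for ribosome biogenesis and adjusted p = 0.272 for Wnt output. By fry only astrocytes and Bergmann glia (fry adjusted p = 0.00119) and Wnt output (fry adjusted p = 0.0139) passed. The lower list means came more from Ptc1+/- array 1 than from array 2, the dimmer of the pair. Against the mean of the SmoM2 groups they stood at -1.43 and -0.43 for astrocytes and Bergmann glia, -2.10 and -1.07 for Purkinje cells, -1.71 and -0.67 for mature granule neurons, -0.75 and -0.21 for oligodendrocytes and -0.61 and -0.06 for synaptic vesicles. Cdon, at -1.73 or lower, with 1 of the 2 arrays at the floor (adjusted p = 0.0051), and Ptch1 were the Hedgehog list members called, and the Hedgehog output list did not pass (adjusted p = 0.12).

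**Figure D4:**
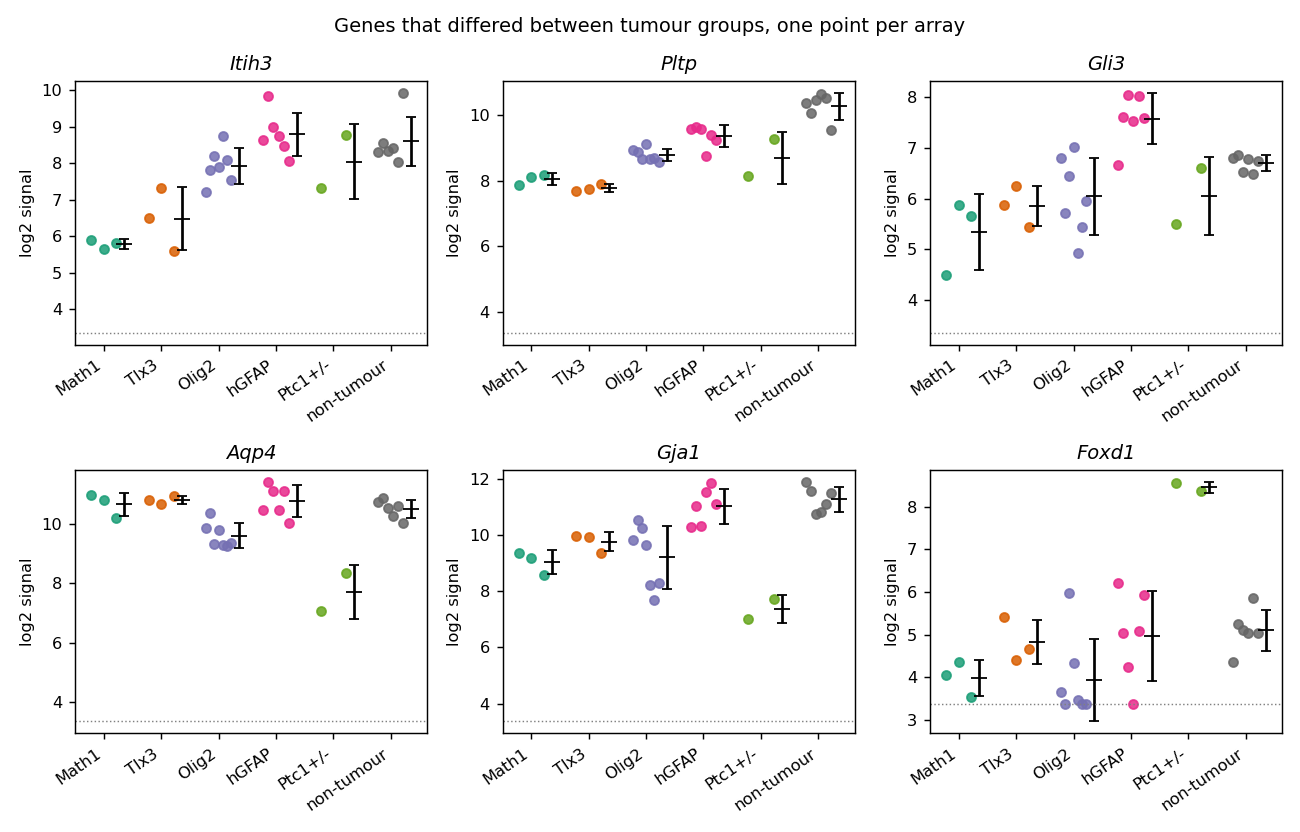
Log2 signal of Itih3, Pltp, Gli3, Aqp4, Gja1 and Foxd1 on each of the 27 arrays by group, with group mean and SD as black bars and the floor of 3.37 as a dotted line. Pltp lies at 8.58 or above on every Olig2 and hGFAP array and at 8.18 or below on every Math1 and Tlx3 array, and Foxd1 lies at 8.37 or above on the 2 Ptc1+/- arrays and at 6.22 or below on the others.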

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

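Values of 126 groups were examined for an array far from the rest, and 12 were picked out, where chance picks about 5% of groups. Array 4 of the hGFAP tumours stood apart for Gli1 (6.36, the nearest at 8.43), and for the list means of Hedgehog output (-0.11, the nearest at 0.49), Hedgehog pathway components (-0.14, the nearest at 0.30) and mitosis (-0.25, the nearest at 0.66). This array 4 also had the highest log2 3' to 5' ratio of any array, at 1.87. Its trimmed mean signal, 74.05, was the lowest of the hGFAP tumours. Whether RNA quality or brightness accounts for its low values was not tested, so they need not mean low Hedgehog activity in that tumour. Array 3 of the hGFAP tumours stood apart for GABAergic interneurons (-1.15, the nearest at -0.53). Control array 6, from a Ptc1+/- mouse, stood apart for Tlx3 (3.63, the nearest at 5.96), other rhombic lip derivatives (-2.46, the nearest at -1.69), neural stem cells (-1.21, the nearest at -0.73), cholesterol synthesis (-0.52, the nearest at -0.09) and, as the highest, DNA replication (-1.82, the nearest at -2.31). Control array 4 was highest for antigen presentation (-0.27, the nearest at -0.50) and control array 5 for choroid plexus (2.20, the nearest at -0.52).

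Tumour groups differed from each other in 35 genes for hGFAP and Olig2 against Math1 and Tlx3, 74 for Ptc1+/- against SmoM2, 404 for hGFAP against Olig2 and 128 among the 4 SmoM2 groups, each by a limma test of the difference. Among 5355 probe sets without a single listed gene, which no comparison above used, 1068 were higher in all tumours than in tissue without tumour and 935 lower, 624 of the former at least 2-fold.

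Random regrouping of the same arrays into groups of the same sizes was set against the counts of comparisons between groups of at least 3 arrays, and not against those of the Ptc1+/- tumours with their 2 arrays (4910 and 74). Chance could be excluded for all tumours (7092 genes, highest of the other splits 1, count of splits reaching the real value 1 of 100), Math1 (5062, highest other 14, 1 of 84), Tlx3 (5451, highest other 15, 1 of 84), Olig2 (6714, highest other 6004, 1 of 100) and hGFAP (5645, highest other 3035, 1 of 100). For hGFAP and Olig2 against Math1 and Tlx3 it could be excluded for the count with all arrays and the processing chosen (35, highest other 3, 1 of 100). That count was 2 to 4 without any 1 of 12 arrays and 2 to 5 with centring, quantile normalization, no floor, no filter, a replicate block or only the compared groups, which is near the highest other split, and the splits were not run again for these settings. Among the 4 SmoM2 groups 3 of 100 splits, the real one included, reached the real count (128, highest other 2060). This is under the limit set beforehand for the count with all arrays and the processing chosen, but it does not exclude chance. The count fell in several other settings and without single arrays, to 41 without Tlx3 array 2, and the splits were not run again for these. A split calling several times the real count points to a structure of the samples other than the driver. Chance could not be excluded for hGFAP against Olig2 (404, highest other 1571, 7 of 100), where the same holds. The Olig2 arrays themselves lay apart on the second principal component. Arrays 5, 6 and 7 were at -48.84, -48.03 and -42.77, with log2 3' to 5' ratios of -0.15, -0.13 and -0.12. Arrays 3 and 4 were at 46.61 and 46.97, with ratios of 1.71 and 1.78, and arrays 1 and 2 at -1.43 and -13.17. Whether this spread accounts for the splits was not tested. For Tlx3 against Math1 the 10 splits were too few (0 by limma, highest other 0, 10 of 10, with 576 genes at an unadjusted p under 0.05).

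The first pattern weighed was the difference between hGFAP and Olig2 tumours, where the tests of RNA quality, dim arrays and brightness leave out arrays or use covariates chosen only after the data were seen. Leaving out the 5 arrays of high 3' to 5' ratio was tried first and decides nothing, since the gap in mean log2 ratio between the groups went from 0.54 to 0.68, whatever the 387 of 404 genes (95.8%) still called and their median difference of 116.5% of its value. With the ratio as a covariate, tried after these, the median was 88.8% of its value (83.6% to 92.4% leaving 1 array out), which argues against a linear trend with the ratio as the whole cause, but the calls were not kept, as 137 of the 404 genes passed, the difference being smaller (0.894 in place of 1.007) at a median standard error of 0.24 in both fits. With brightness as a covariate it was 95% (91.3% to 99.2%, a median of 0.956, with 284 of the 404 genes among 308 called), which argues against a linear trend with brightness, whereas without the 7 dimmest arrays it was 75.6% (65.5% to 77.1%), with 2 Olig2 arrays left, so dim arrays could account for part of it and stay open. The driver line as a biological explanation stays open as untested.

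The second pattern was the set of 68 genes lower in Ptc1+/- than in SmoM2 tumours, where the test with array brightness as a covariate was chosen only after the data were seen. Less normal tissue in the Ptc1+/- samples predicts genes that are also lower in SmoM2 tumours than in tissue without tumour. This held for 55.9% (38 of 68), against 25.3% of all genes, and 12 of the 68 were higher there. The SmoM2 means enter both comparisons with opposite sign, so picking genes high in SmoM2 tumours tends to lower this share. The 25.3% of all genes is therefore not a like reference. Leaving 1 array out and calling the lower genes anew each time, the prediction held for 33.6% to 59.2% of the genes then called. The range thus covers different gene sets, and less normal tissue stays open. With array brightness as a covariate the median difference was 83.9% of its value (80.5% to 93.6%, from -1.78 to -1.49), which argues against a linear trend with brightness as the whole cause. The calls were not kept, as 6 of the 68 genes passed with the covariate, the difference being smaller and its median standard error going from 0.36 to 0.40. That the genotype itself lowers these genes is a hypothesis and stays untested.

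The third pattern was the higher level of mural and mesenchymal genes in hGFAP and Olig2 tumours, where all tests were chosen or changed only after the result was seen. The median difference of the 11 genes was 102.3% of its value without the arrays of high ratio (92.1% to 113%, the gap in mean log2 ratio going from 0.55 to 0.12) and 112.7% without the dimmest arrays (95.6% to 162%, the gap in mean log2 brightness going from -0.79 to -0.24), which argues against both as the whole cause. A random difference between arrays stays open, since the list was picked out of 34 and its exact two-sided permutation p of 0.0028 over 27132 splits became an adjusted p = 0.094 over the lists. Camera with an estimated correlation gave an adjusted p = 0.283, and 7 of 13 hGFAP and Olig2 arrays lay above every Math1 and Tlx3 array. Vessel or meningeal tissue in the samples and the driver line stay open as untested.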

How the results depend on the processing

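Of 421 counts and shares 338 stayed within their limits, 80 moved and 3 were weaker. Of 20433 values of single genes 19557 kept direction and call, 809 were weaker, 65 stronger and 2 reversed, and of 714 list values 644 stayed, 46 were weaker and 24 stronger. Counts against tissue without tumour stayed within 1.5 times their value, although array weights gave 7111 for Math1, 7868 for Tlx3 and 3830 for Ptc1+/-. The exception was testing every probe set on its own, which tests more features: 14087 for all tumours, 9665 for Math1, 10135 for Tlx3, 13479 for Olig2, 10968 for hGFAP and 9369 for Ptc1+/-. The other causes were not tested, and the covariates and the sets of high-ratio and dim arrays were chosen after seeing the data. The reversed genes were Fen1 (0.85) and Nes (1.02), with the mean of their probe sets, neither called with a single probe set. For hGFAP and Olig2 against Math1 and Tlx3 (35) the counts were 4 with quantile normalization, 2 centred on array medians, 4 without a floor, 4 without a filter, 11 with every probe set, 2 with only the compared groups, 8 with plain eBayes, 520 with array weights, 5 with a replicate block, 10 with the 3' to 5' ratio and 6 with brightness as a covariate, 4 without the high-ratio arrays and 9 without the dimmest. For Ptc1+/- against SmoM2 (74) they were 124 with quantile normalization, 126 without a filter, 47 with the mean of probe sets, 24 with only the compared groups, 8 with array weights, 10 with brightness and 194 without the dimmest arrays. For hGFAP against Olig2 (404) they were 680 with every probe set, 0 by limma with only the compared groups, 128 with the block, 151 with the ratio, 1768 without the high-ratio arrays and 0 without the dimmest. Among the 4 SmoM2 groups (128) they were 77 centred on medians, 11 with only the compared groups, 1540 with array weights, 26 with the block, 38 with brightness and 698 without the high-ratio arrays, and for Tlx3 against Math1 (0, with 576 at an unadjusted p under 0.05) 1 with every probe set and 101 with array weights. The share between SmoM2 groups was 24.4% with a correlation distance, no longer past the threshold. Leaving out each array gave 2 to 81, 35 to 137, 82 to 1395, 41 to 455 and, for Tlx3 against Math1, 0 to 0 genes in these comparisons, 6617 to 7233 for all tumours, 4041 to 4974 for Math1, 4263 to 5286 for Tlx3, 6304 to 6840 for Olig2, 5208 to 5562 for hGFAP and 3613 to 4791 for Ptc1+/-, 2499 to 3334 shared genes, and a share of 23.1% to 27.9%. Residuals of arrays with the same number had a median correlation of 0.034 over 49 pairs (-0.34 to 0.28), so the numbers do not pair samples. Signals near the floor limit what dim genes can show.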

Other observations

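The sexes of the animals, not given in the labels, were read from Xist and genes of the Y chromosome. Xist was at 12.37 on Math1 array 3 and 5.72 on Math1 array 1, where Eif2s3y stood at 3.37 and 7.73. In the Ptc1+/- tumours Xist was 10.83 on array 1 and 6.05 on array 2.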
